A study of Mus musculus with 8 samples.

How the data were processed

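Back-spliced reads of circRNAs were measured in heart tissue of male wild-type mice, 4 after a sham operation and 4 after transverse aortic constriction (TAC), 8 weeks after surgery. Circular RNA was extracted from the tissue with a commercial kit and a company made the libraries, per the labels' protocols, while the labels give the molecule as total RNA. The submitters' processing notes name the genome build mm10 and the tools HISAT2, StringTie and DESeq2 without versions or roles. The circRNA caller, the removal of ribosomal or linear RNA and the read length are not given in the sources used here. Libraries are named by group and by a replicate number in accession order, which pairs no sham mouse with a TAC mouse.

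The deposited values have the unit signal: the authors' back-spliced reads per circle divided by 1 size factor per library. The labels do not say so; it follows from the values. Within a library each value was a whole multiple of the smallest one (100% of values within 0.001), and the size factors implied by these steps equalled the median-of-ratios factors that DESeq2 computes from the recovered reads. Whole reads were therefore recovered for every circle and library. Size factors ran from 0.173 to 5.14 and read totals from 1119 to 100142. No value is scaled by circle length. The design fixed before the data were examined assumed raw counts, with a test for normalised values in reserve; since the deposited unit was not counts, the reserve test became the main one. The table held no column without a sample and no linear reads, so a ratio of circular to linear RNA was not analysed here.

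The main test was limma with an intensity trend on log2(value + 0.195), the pseudocount being the smallest value above 0, for circles above 0 in at least 4 of 8 libraries. Fold changes of limma are on that scale. In the main fits of circles and hosts, limma's SE and p-values followed the intensity trend over all features, not the spread of a single feature between mice. As an alternative added once the unit was known, the count test of the design, the edgeR quasi-likelihood test (TMM, robust) was run on the recovered reads of circles kept by a filter with a minimum count of 5 and a minimum total of 15. DESeq2 with its own size factors and limma-voom with sample quality weights were run as further alternatives. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Replicates are separate mice, 4 per group per the labels' protocols. Host gene sums add the values of all circles that the table assigns to a gene. Some gene names of the table had been turned into dates by a spreadsheet, and none of them is in a gene list.

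Gene lists fixed before the data were examined covered the sarcomere and Z-disc, calcium handling and ion channels, intercalated disc and costamere, extracellular matrix and TGF-beta, the stress and fetal gene program, hypertrophic signalling, fatty acid and mitochondrial metabolism, RNA-binding and splicing factors, chromatin regulators, ubiquitin ligases with deubiquitinases and autophagy genes, circRNA hosts studied in heart or conserved, and markers of fibroblasts, endothelial cells, smooth muscle and pericytes, leukocytes, adipocytes, Schwann cells and neurons, and erythroid cells. Of these 18 lists, those with at least 5 tested hosts were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Library-level measures were compared by exact permutation tests, and shares of single libraries carry 95% Wilson intervals.

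The named circles follow a rule fixed before the data were examined. It takes circles past the threshold, filled up to 6 per direction by the smallest unadjusted p, the 6 with the largest mean in normalised reads, the most abundant circle of Slc8a1, Ryr2, Ttn, Hipk3, Zfp609, Foxo3, Mlip, Camk2d, Nfix and Fndc3b where tested, the 3 hosts with the smallest p per direction (5 if they pass), and per list up to 3 members that pass or else the 2 with the largest mean. No circle of Foxo3 met the filter. Not every gene that the rule picks is named in the text. After the results were seen, the 8 largest changes per direction were also taken from the edgeR calls. Genes named beyond it as calls of a fixed list were chosen after their values were seen. Overlapping genes and antisense partners were not separated, as the strand of the libraries is not given in the sources used here.

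Coordinates are those of the table in mm10, given from 1. Spliced lengths, exon numbers and coding parts come from GENCODE M21 transcripts matched to the isoform or exon count that the table lists, with both ends of a circle at exon borders, which gave a length for 94.9% of circles and 98.9% of the circles tested by limma. The length trend of a library was a robust loess (span 0.5) of the deviations from each circle's mean on log2 spliced length. Scripts were tested on simulated data with known changes. Simulated libraries had the real size factors, which do not fix the read totals, and 1 common dispersion for all circles. No simulated library resembled the other group, and changed circles were drawn from the most abundant ones. On 3238 unchanged circles limma made 0 calls and edgeR 1 of 729 tested. Removing a simulated length trend took the rank correlation of fold change with length from 0.459 to 0.00467, over 3201 circles. Camera called a raised list (2705 hosts simulated) and 0 lists among 16 in unchanged data.

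Alternatives covered the pseudocount, the filter, the scaling, the tool, each library left out in turn, the detection limit and thinning to the smallest library. Once the unit was known, edgeR, the count test of the design, was added on the recovered reads. Those added after the data were seen were the rescaling of deposited values, removal of the length trend, an unadjusted threshold for DESeq2, edgeR without each library in turn, and the removal of the 2 libraries under 5000 reads. Depth limits the precision: a circle with 0 reads in a library allows up to 3 reads at 95% confidence, which is far more in normalised reads for the shallow libraries than for the deep ones. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.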

Results

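Circular RNAs (circRNAs), closed loops formed when the end of an exon is spliced back to the start of the same or an earlier exon, were profiled in hearts of male wild-type mice. The mice had undergone transverse aortic constriction (TAC) or a sham operation 8 weeks earlier. TAC narrows the aortic arch, so that the left ventricle ejects against a raised pressure. Each group held 4 mice with 1 library each, and the comparison asks which circles of the heart differ under lasting pressure overload. The table listed 27391 circles from 6492 host genes, of which 26065 were typed as circRNA and 1326 as intronic circles (ciRNA). Together the libraries held 254236 back-spliced reads, the reads that cross the closing junction of a circle. Sham replicates 1 to 4 had 40796, 3963, 17890 and 100142 reads, and TAC replicates 1 to 4 had 33132, 1119, 21074 and 36120. Most circles were rare: 16891 (61.7%) were seen in 1 library only, 12725 rested on a single read in the whole table, and 115 were seen in all 8 libraries. The most abundant circle came from Slc8a1 in TAC replicates 1, 3 and 4 and in sham replicate 2, from Cpeb3, Arhgap32 and Asph in sham replicates 1, 3 and 4, and from Ogdh in TAC replicate 2.

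The 2 shallowest libraries also stood apart from their groups in the length of their circles. At the median read, the spliced length was 394, 491, 368 and 353 nt in sham replicates 1 to 4 and 542, 334, 519 and 498 nt in TAC replicates 1 to 4. Circles over 1000 nt held 13.7% of reads in sham replicate 2 (95% Wilson interval 12.6 to 14.8%) against 2.10 to 2.74% in the other sham libraries. Circles under 300 nt held 32.9% of reads in TAC replicate 2 (30.2 to 35.8%) against 7.25 to 9.84% in the other TAC libraries. Neither library matched the other group throughout. Circles over 1000 nt held 8.62% of reads in TAC replicate 2 (7.10 to 10.4%), nearer the 10.9 to 16.5% of the other TAC libraries than the 2.10 to 2.74% above. Circles under 300 nt held 12.5% in sham replicate 2 (11.5 to 13.6%) against 17.3 to 31.2% in the other sham libraries. These intervals cover counting error only, since reads amplified by PCR are not independent molecules.

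**Figure D1:**
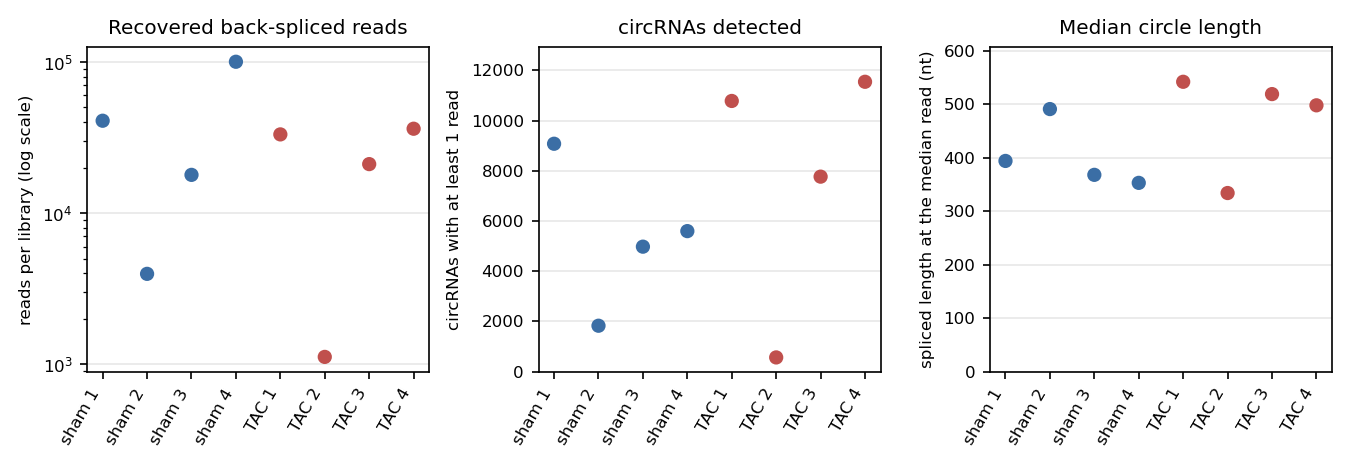
Recovered back-spliced reads (log axis), circRNAs detected and spliced circle length at the median read, 1 point per library, sham in blue and TAC in red. Sham replicate 2 (3963 reads) and TAC replicate 2 (1119 reads) were the shallowest, and their median lengths, 491 and 334 nt, lay on the side of the other group.

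Among single circles, the exon 2 circle of Slc8a1, the sodium-calcium exchanger of the cardiomyocyte membrane, rose in TAC hearts. Its level was 475 ± 379 normalised reads in TAC against 84.6 ± 128 in sham (SD, n = 4 each), with a limma log2 fold change of 3.03 ± 0.53 (SE, adjusted p = 4.4e-05). This SE and p rest on the intensity trend over all circles, not on the spread of this circle between mice. With a filter of 10 reads in 4 libraries the SE was 1.05. This circle is exon 2 of 11, at chromosome 17, 81647809 to 81649638 (mm10), 1830 nt long with 31 nt of 5' UTR, the start codon and 1799 nt of coding sequence. The TAC libraries stood at 952.5, 57.7, 558.9 and 330.7 and the sham libraries at 24.6, 277.1, 20.7 and 15.95, so that 3 of 4 TAC libraries exceeded every sham library. With edgeR on the recovered reads the log2 fold change was 2.74 ± 0.95 (adjusted p = 0.0356). The call was lost without TAC replicate 1 (log2 fold change 2.50), with DESeq2 (2.55, adjusted p = 0.112), with values rescaled by TMM (2.92, adjusted p = 0.872), with a filter of 10 reads in 4 libraries (3.03, adjusted p = 0.827), and after the length trend of each library was removed (1.36 ± 0.74, adjusted p = 0.583).

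No other circle of the 3735 tested passed limma's test, so 1 was higher and 0 were lower in TAC. At an unadjusted p under 0.05 limma gave 152 circles, 73 higher and 79 lower, where chance alone gives about 186.75. The groups did not overlap for 116 of the 3735 circles, where chance gives 106.7. Reads were also simulated from the real size factors, with the changed circles drawn from the most abundant ones. On these reads limma found 12.1% of 198 circles changed 4-fold and 72.1% of 190 changed 16-fold. In the same simulation edgeR found 37.0% of 138 and 100% of 144. All simulated circles had 1 common dispersion (0.316), with no length trend and no library resembling the other group. These rates may therefore be too high for the real libraries and for rarer circles. The limma count was 0 without TAC replicate 1 (84 at an unadjusted p under 0.05), 6 without sham replicate 2 and 41 without TAC replicate 2. Without the 2 libraries under 5000 reads, an alternative chosen after the data were seen, limma called 1037 of 5809 circles, 851 higher and 186 lower. The filter then let in circles seen in every remaining library of 1 group and in none of the other. Such circles were fully separated beforehand. The 2 libraries left out are also those whose circles correlated better with the other group. With the same libraries left out, edgeR called 188 higher and 156 lower.

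With edgeR on the recovered reads, 94 of 717 circles changed, 53 higher and 41 lower in TAC, and 204 had an unadjusted p under 0.05 where chance gives about 35.85. Among the circles with the largest edgeR rises were exons 2 to 8 of the kinase gene Stk39 (log2 fold change 4.70 ± 1.30, adjusted p = 0.0113), exon 2 of Shoc2, a scaffold of Ras signalling (4.68 ± 1.05), and exons 7 to 10 of the Z-disc gene Pdlim5 (4.09 ± 0.93). Circles of Tnrc6a, a partner of Argonaute in microRNA silencing (4.17 ± 1.43), Fam193a (4.12 ± 1.19), H6pd, an enzyme of the endoplasmic reticulum (3.98 ± 1.20), and Zfp609 (exon 2, 3.84 ± 0.92) rose as well. Several of these rises lay near the floor. Sham replicates 1 to 4 had 0, 1, 0 and 0 reads for Stk39 and for Tnrc6a, and 1, 1, 0 and 0 for Shoc2 and for H6pd. TAC replicates 1 to 4 had 14, 0, 5 and 9 reads for Stk39 and 8, 0, 4 and 7 for Tnrc6a. Normalised means in TAC and sham were 5.32 and 1.14 for Stk39 and 3.63 and 1.14 for Tnrc6a. The Pdlim5 and Zfp609 circles had more reads in TAC. The largest falls were in circles of Uxs1, an enzyme of nucleotide sugar synthesis (exons 2 to 5, −5.40 ± 1.10, adjusted p = 0.000686), Zcchc4 (−4.75 ± 1.16), the spliceosome gene Prpf6 (−4.64 ± 0.99), and Arhgap32, a GTPase-activating protein (exons 3 to 4, −4.22 ± 1.30). Circles of Cd36, the fatty acid transporter (−3.89 ± 0.96), the arginine methyltransferase gene Carm1 (−3.86 ± 1.09), Cdk17 (−3.62 ± 0.90) and the nuclear pore gene Nup155 (−3.48 ± 0.99) also fell. The called circles differed in length, with a median of 775.5 nt for the higher and 290 nt for the lower against 417 nt for all circles in the edgeR test. DESeq2 called 23 circles (14 higher, 9 lower), of which 12 were among the 94, and limma and edgeR shared 1.

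The edgeR count changed strongly with the library left out. It was 62, 248, 39 and 34 without sham replicates 1 to 4 in turn, and 9, 230, 0 and 9 without TAC replicates 1 to 4. Without TAC replicate 3, where edgeR called 0, it gave 154 circles at an unadjusted p under 0.05 and limma called 1. Without the 2 libraries under 5000 reads edgeR called 344 circles, 188 higher and 156 lower, and 92 of the 94 were among them. The split of 53 higher and 41 lower was 55 and 27 with RLE size factors and 25 and 36 with library totals alone. With the length trend of each library as an offset it was 6 higher and 19 lower, 18 of these 25 circles being among the 94.

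By the fixed gene lists, 3 of 17 circles of sarcomere and Z-disc genes tested by edgeR rose in TAC and 1 fell. Those that rose included the Pdlim5 circle and exons 104 to 110 of Ttn, the gene of the giant spring protein titin (chromosome 2, 76863274 to 76868085, 780 nt, all coding; log2 fold change 2.63 ± 0.86, adjusted p = 0.0281). Of 15 circles of calcium handling and ion channel genes 2 rose, those of Slc8a1 and of Ryr2, the calcium release channel of the sarcoplasmic reticulum (exons 24 to 29, chromosome 13, 11759671 to 11785141; 2.52 ± 0.82, adjusted p = 0.0270). Of 10 circles of intercalated disc and costamere genes 3 rose, among them circles of Sorbs2, and of 14 circles of hypertrophic signalling genes 2 rose, from the insulin receptor Insr and Igf1r. Of 7 circles of fatty acid and mitochondrial metabolism genes 2 fell, those of Cd36 and Hadhb, a subunit of the mitochondrial trifunctional protein. Of 15 circles of RNA-binding and splicing factors 3 rose, from Rbm20, a regulator of titin splicing, Rbm33 and Tnrc6a, and of 16 circles of chromatin regulators 1 rose, from Ash1l. Among endothelial markers 1 of 9 circles rose (Dysf) and 1 fell (Npr3). These counts carry no set test of their own, and with the length offset only the Pdlim5 and Cd36 circles of those named here by list stayed called.

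Other abundant or often studied circles had these values. Exon 2 of Nfix, a nuclear factor I transcription factor, stood at 241 ± 128 in TAC and 62.3 ± 41.5 in sham (chromosome 8, 84771784 to 84772315, all coding; limma log2 fold change 1.89 ± 0.55, adjusted p = 0.834). The circle of exons 8 to 10 of Cpeb3, a translational regulator, stood at 38.9 ± 20.6 in TAC and 160 ± 77.7 in sham (limma −2.07 ± 0.64, adjusted p = 0.834; edgeR −2.27, adjusted p = 0.0624). The circle of exons 2 to 6 of the ubiquitin-conjugating enzyme Ube2d2a stood at 10.3 ± 7.001 in TAC and 55.8 ± 29.8 in sham, and fell by 2.48 on the log2 scale in the edgeR test (adjusted p = 0.0310). Exon 2 of Zfp609 stood at 43.1 ± 31.5 in TAC and 6.40 ± 10.9 in sham, with 0 reads in TAC replicate 2. It passed in edgeR but not in limma (2.94 ± 1.49), and passed in limma without TAC replicate 2 (4.98, adjusted p = 2.3e-05). The Arhgap32 circle of exons 14 to 18 had a limma log2 fold change of −2.47 ± 0.92, and the Arhgap10 circle of exons 14 to 18 one of −2.92 ± 1.01. Without TAC replicate 2, where both had 0 reads, these were −0.49 and −1.14, and without sham replicate 2 the Arhgap32 circle was called lower (−3.74, adjusted p = 0.00101). Circles of Snd1, Kcnt2 and exons 85 to 132 of Ttn were listed at 0 in all sham libraries, at means of 5.19 ± 3.21, 4.07 ± 2.95 and 4.68 ± 4.85 in TAC. Reads in TAC replicates 1 to 4 were 11, 1, 6 and 1 for Snd1. They were 1, 1, 7 and 4 for Kcnt2 and 6, 2, 2 and 1 for this Ttn circle. Circles of Tmbim6 and Ube2g2 were listed at 0 in all TAC libraries, at 13.8 ± 14.4 and 6.16 ± 5.34 in sham. A circle at 0 in a whole group passes limma's filter only with reads in all 4 libraries of the other. This full separation was thus fixed by the filter, and limma's adjusted p was 0.834 for each of these circles. The Ogdh circle of exons 3 to 4, from the first subunit of the 2-oxoglutarate dehydrogenase complex, was at 116 ± 32.9 in TAC and 146 ± 69.9 in sham (limma −0.23 ± 0.51). Exon 2 of Hipk3 had a limma log2 fold change of 0.11 ± 1.05, and circles of Mlip, Camk2d and Fndc3b had −1.03 ± 1.18, 0.28 ± 1.51 and 0.22 ± 1.57. The Rad52 circle was at 102 ± 70.3 in TAC and 73.6 ± 75.9 in sham while its limma log2 fold change was −1.001 ± 0.83, TAC replicate 2 being at 0. Without TAC replicate 2, limma also called the circles of Nfix (2.52), Ttn (exons 104 to 110, 3.62), Ryr2 (3.15), Hipk3 (2.33) and Rad52 (1.36) higher, and those of Cpeb3 (−1.74), Ube2d2a (−1.88), Uxs1 (−5.60) and Tmbim6 lower. Signs of Ogdh, Rad52, Hipk3, Mlip, Camk2d and Fndc3b turned under some settings.

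**Figure D2:**
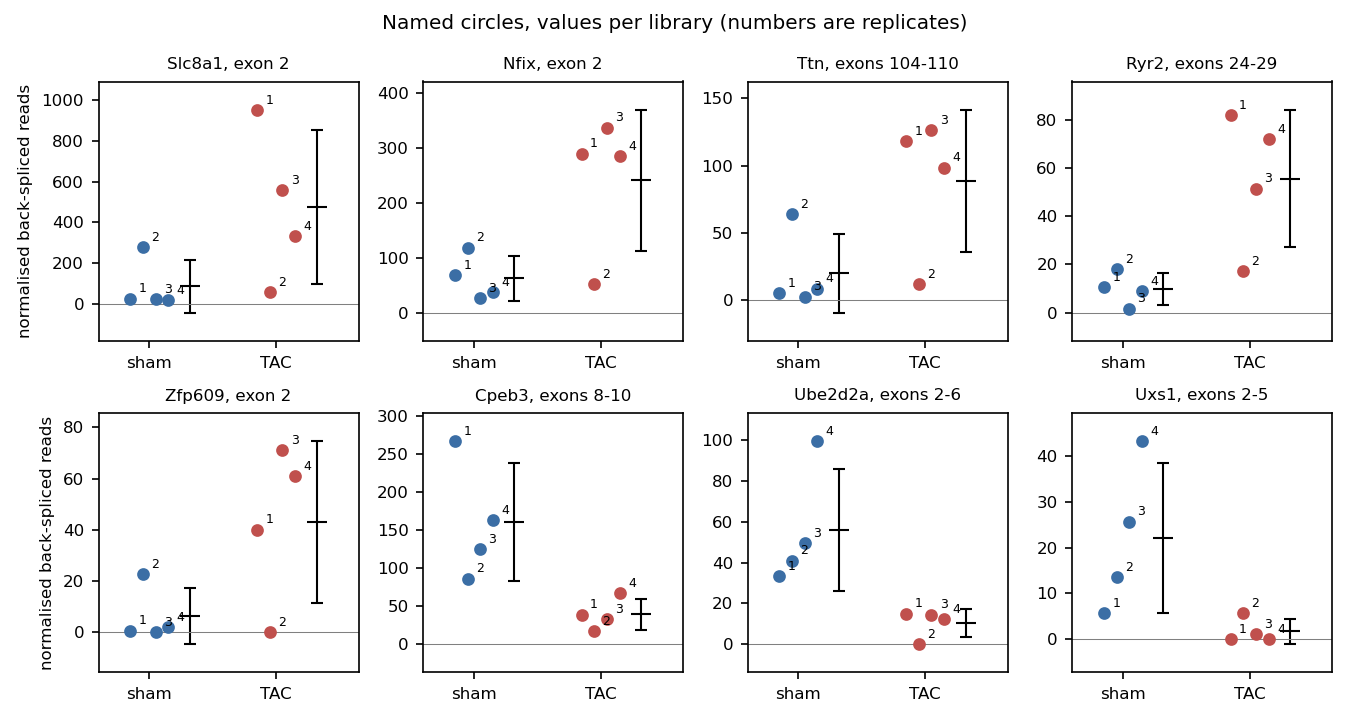
Normalised back-spliced reads of 8 named circles in each library, with the replicate number beside each point and the mean ± SD as a bar, sham in blue and TAC in red. For Slc8a1, Ttn and Zfp609 sham replicate 2 lies above the other sham libraries and TAC replicate 2 below the other TAC libraries.

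**Figure D3:**
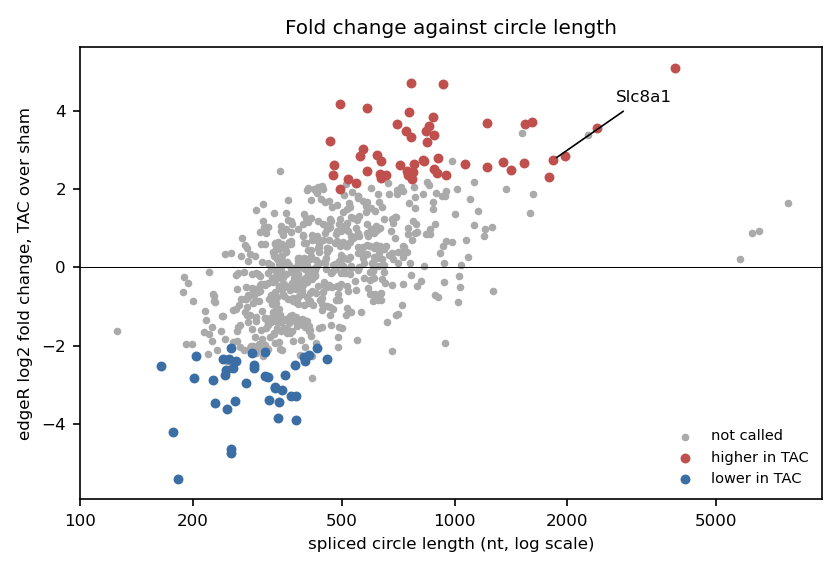
edgeR log2 fold change (TAC over sham) against spliced length in nt (log axis) for each circle in the edgeR test, with calls higher in TAC in red and lower in blue. The higher calls have a median length of 775.5 nt and the lower calls of 290 nt.

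Summed over all circles of a host gene, the output of Slc8a1 rose in TAC, to 548 ± 412 normalised reads against 105.9 ± 139 in sham (n = 4 each; limma log2 fold change 2.66 ± 0.40, adjusted p = 8.4e-08; edgeR 2.37, adjusted p = 0.0173). The limma SE and p of this sum rest on the intensity trend, not on its spread between mice. The exon 2 circle made up 85.6% of this sum, and the other 13 circles gave a limma log2 fold change of 1.66 ± 0.85. Slc8a1 was the 1 host of 2967 that limma called higher, and 0 were lower. At an unadjusted p under 0.05 limma gave 90 hosts, where chance gives about 148.35, DESeq2 called 42 (15 higher, 27 lower) and edgeR called 84 of 1020 (34 higher, 50 lower). Hosts just short of limma's threshold were Nfix (1.91 ± 0.47) and Ttn (1.59 ± 0.40), each with an adjusted p of 0.0612. The sum over Cpeb3 circles fell by 2.21 in the edgeR test (adjusted p = 0.0221; limma −1.80 ± 0.50, adjusted p = 0.235), as did that over Ube2d2a (edgeR −2.62, adjusted p = 0.00424; limma −3.44 ± 1.05, or −1.89 with an adjusted p of 0.0388 without TAC replicate 2), while Ube2g2 had 0 reads in TAC. The call of Slc8a1 held without each library in turn (2.15 to 3.50), but was lost with DESeq2 (2.19, adjusted p = 0.0553), with values rescaled by TMM (2.55, adjusted p = 0.999) and with the filter of 10 reads in 4 libraries (adjusted p = 0.988). The limma count was 6 without sham replicate 2, 28 without TAC replicate 2 and 221 of 3648 (185 higher, 36 lower) without the 2 libraries under 5000 reads. Reads in the remaining libraries of 1 group alone could then meet the filter. The edgeR count of 84 became 230 and 47 without sham replicates 2 and 3, 19 without sham replicate 4, 11 without TAC replicate 1 or 3, 20 without TAC replicate 4 and 299 without the 2 shallow libraries.

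Hosts of the sarcomere and Z-disc list lay higher in TAC as a set. Of 22 tested hosts 16 had a positive and 6 a negative log2 fold change, with a median of 1.20 against 0.13 for all hosts (camera adjusted p = 0.00824). The call was lost with the correlation within the list estimated (0.256): adjusted p = 0.994 with an estimated correlation. None of the 22 passed over all hosts, 2 had an unadjusted p under 0.05 and edgeR called 0 of the 11 it tested, while 1, Ttn, passed limma adjusted over the list alone. Pdlim5 of this list had a log2 fold change of 0.91 ± 0.76. The spliced length of these hosts' circles had a median of 595 nt against 493 nt for all hosts. The list median was 0.35 and the call was lost without TAC replicate 4, and on single circles in place of host sums it was 0.998 (adjusted p = 0.00281), or −0.02 with the length trend removed. Without sham replicate 2, and without TAC replicate 2, 2 lists passed, and without the 2 libraries under 5000 reads the sarcomere list (median 1.91, adjusted p = 0.000169) and the list of known circRNA hosts (adjusted p = 0.000503) passed.

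The other lists did not pass. Hosts of calcium handling and ion channels had 12 positive and 10 negative fold changes (median 0.44, camera adjusted p = 0.671), with 1, Slc8a1, passing over all hosts and adjusted over the list alone. The 34 hosts of circRNAs studied in heart or conserved between species had 18 positive and 16 negative (median 0.14, adjusted p = 0.321); 1 passed over all hosts and 3, Slc8a1, Ttn and Nfix, adjusted over the list alone. Intercalated disc and costamere hosts had 12 positive and 9 negative (median 0.09; Utrn −0.18, Sorbs2 0.05), and extracellular matrix and TGF-beta hosts 12 and 5 (median 0.79, adjusted p = 0.359; Ltbp1 −0.23, Smad4 −0.99). Hypertrophic signalling had 20 positive and 23 negative (median −0.03; Insr 1.61, Camta1 −0.15), fatty acid and mitochondrial metabolism 13 and 11 (median 0.15; Ogdh −0.15), and RNA-binding and splicing factors 22 and 16 (median 0.32; Qk 1.22, Cnot2 −0.74). Chromatin regulators had 31 positive and 23 negative (median 0.17; Cdyl 0.40, Med13l −1.17), and ubiquitin ligases, deubiquitinases and autophagy genes 20 and 27 (median −0.37; Usp3 −0.85, Ube3a −2.16, the latter called lower by edgeR, adjusted p = 0.0221). Camera pointed down for intercalated disc, hypertrophic signalling, metabolism and adipocyte lists although the median or mean of each was above 0. Without the 2 libraries under 5000 reads it pointed up for intercalated disc (adjusted p = 0.0649), hypertrophic signalling (0.347) and adipocyte lists (0.664). For metabolism it still pointed down (0.908). On these hosts edgeR called Igf1r (1.96), Tnrc6a (2.77), the DNA demethylase gene Tet3 (3.53), Zfp609 (3.95) and Aff1 (2.99) higher, and Prkd1 (−2.26) and Hadhb (−2.17) lower. In the stress and fetal gene program 3 hosts could be tested, all with positive values, among them Uck2 (1.98) and Nav2 (1.81), and no set test was run.

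No list of hosts that mark the other cell types of the heart passed. Fibroblast markers had 7 positive and 3 negative fold changes (median 0.49; Scn7a 0.66, Lama2 −1.23), endothelial markers 8 and 13 (median −0.54; Dysf 1.17, Ccdc141 −0.63), and smooth muscle and pericyte markers 8 and 2 (median 0.54; Abcc9 0.41, Ano1 0.32). Leukocyte markers had 3 positive and 9 negative (median −0.49; F13a1 −1.05, Adgre1 −0.27), adipocyte markers 5 and 2 (median 0.52; Ghr 1.36), and erythroid markers 5 and 1 (median 1.16; Tfrc 0.53, Ubr2 −2.60). Camera's adjusted p was 0.359 or higher for each of these 6 lists, no member passed limma's test over all hosts or adjusted over the list alone, and 1 erythroid host had an unadjusted p under 0.05. edgeR called 1 endothelial host, Npr3, a clearance receptor of natriuretic peptides, lower in TAC (−2.18 ± 0.67, adjusted p = 0.0256). Of Schwann cell and neuronal markers 2 hosts could be tested, Cdh19 (−0.82) and Rims2 (0.07).

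Library-level measures were compared by exact two-sided permutation tests over the 70 assignments of 4 and 4, whose smallest possible p is 0.0286. TAC libraries held 7668 ± 5008 detected circles and sham libraries 5373 ± 2973 (difference 2295.5, exact p = 0.429), a difference that was −13.7 with every library thinned to 1119 reads. Thinned so, TAC replicates 1, 3 and 4 held 845 to 869 circles and the sham libraries 776 to 821, while TAC replicate 2 held 567. Total reads were 22861 ± 15887 in TAC and 40698 ± 42439 in sham (exact p = 0.543), and the sign of the difference turned without sham replicate 4 (1978). The 10 most abundant circles took 8.94 ± 1.97% of reads in TAC and 7.44 ± 0.976% in sham (exact p = 0.343). Intronic circles, lariat-derived RNAs of introns, took 1.49 ± 0.273% of reads in TAC and 0.975 ± 0.199% in sham, a difference of 0.51 percentage points (exact p = 0.0571, adjusted p = 0.210 over 11 tests). Among measures chosen after the data were seen, the share of detected circles with a single read was 61.1 ± 3.24% in TAC and 38.2 ± 22.2% in sham (exact p = 0.0286, adjusted p = 0.210), sham replicate 4 being at 5.61%. Circles over 1000 nt took 12.2 ± 3.32% of reads in TAC and 5.28 ± 5.61% in sham (exact p = 0.114), and circles under 300 nt 14.5 ± 12.4% and 21.8 ± 8.49% (exact p = 0.314). None of the 11 measures passed after adjustment.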

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

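Of the tests in this part, the count of libraries whose median circle length lies on the other group's side was chosen after the result was seen, and so was the reading of the label tests as undecided.

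In 76 groups of 4 libraries, 9 held a library far from the other 3. About 1 in 20, or 3.8 groups, is flagged by chance if values are normally distributed. Normalised reads need not be, and the groups are not independent, as the sums of Slc8a1 and Ttn contain their circles. Sham replicate 2 was the distant library in 7 of the 9. Its circles over 1000 nt took 13.7% of reads (2.10 to 2.74% in the other sham libraries), its Slc8a1 exon 2 circle stood at 277.1 normalised reads (15.95 to 24.6), its Ttn circle of exons 104 to 110 at 63.6 (2.48 to 8.37), its Rad52 circle at 186 (21.5 to 47.5) and its Zfp609 circle at 22.7 (0 to 2.14). All circles of Slc8a1 summed to 313.5 there (24.7 to 60.7) and those of Ttn to 299.8 (44.7 to 69.4). In TAC replicate 2 circles under 300 nt took 32.9% of reads (7.25 to 9.84% in the other TAC libraries). In sham replicate 4 each detected circle had 17.9 reads (2.17 to 4.49 in the other sham libraries).

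A first pattern is that sham replicate 2 and TAC replicate 2 each resemble the other group: the mean correlation over circles was 0.0995 with own and 0.44 with other for the first, and 0.148 and 0.310 for the second, against the 3 deeper libraries of each group. Low depth alone is argued against, since thinned to 3963 or to 1119 reads all 6 of 6 deeper libraries stayed nearer their own group in 50 of 50 draws. The length profile stays open, as the difference of correlations varied with length: for sham replicate 2 it was 0.0962 (95% interval −0.0199 to 0.204) under 350 nt, 0.264 (0.156 to 0.369) from there to 600 nt and 0.545 (0.431 to 0.661) beyond, and for TAC replicate 2 it was 0.198, 0.0645 and −0.262 (−0.389 to −0.108). These intervals come from resampling circles and leave out variation between mice. Both correlations with the other group lay below every thinned library of that group (lowest 0.601 and 0.401), the bound set beforehand against a wrong label, but these draws hold read sampling and no difference in preparation, so the bound was too strict and a wrong label for either library cannot be told apart from a different preparation. With the 2 labels exchanged limma called 47 circles against 1 by label and edgeR 218 against 94, the highest of all splits in edgeR, while another split gave 366 with limma and 0 with edgeR, so an exchange may or may not have happened.

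A second pattern is that circles higher in TAC are longer, with slopes of log2 fold change per doubling of spliced length of 0.865 in limma and 1.31 in edgeR. In these 8 libraries a change of host gene expression alone is argued against, since circles of 1 gene should then move alike. Among circles of the same host the limma slope was 0.851 (95% interval 0.731 to 0.983, from resampling 798 hosts). That interval leaves out variation between mice. A length bias that differs between libraries whatever their group stays open: 2 of 8 libraries had a median length on the other group's side, but this was known when the test was chosen and lends no support of its own. TAC itself, as an influence on which circles form or persist, stays open and was not tested apart from that bias.

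The last pattern is the rise of the Slc8a1 exon 2 circle. Length bias between libraries is not excluded: with each library's length trend removed the log2 fold change went from 3.03 ± 0.53 to 1.36 ± 0.74 (SE), and the call ended because the estimate shrank and its error grew. A change of all Slc8a1 circles alike cannot be told apart from one of this circle, as the sum of the other 13 gave 1.66 ± 0.85 and the difference of 1.36 ± 1.003 lies within 2 of its standard errors, the bound set beforehand. A response of Slc8a1 circles to pressure overload remains a hypothesis.

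Chance was tested over the 35 splits of the 8 libraries into 4 and 4. For circles called by limma 4 splits, the real one included, gave at least the real count of 1 (highest other 366), and for hosts 7 splits gave at least 1 (highest other 165). For gene lists 16 splits gave at least 1 (highest other 3). For edgeR's 94 circles 2 splits, the real one included, gave as many (highest other 218, with the 2 shallow libraries exchanged). In every other split edgeR called 0 circles, and the exchanged split still sets the deep sham against the deep TAC libraries. By the bound set beforehand, chance is not excluded for any of these 4 counts. The split with 366 calls puts the 4 libraries with the most detected circles (sham replicate 1 and TAC replicates 1, 3 and 4) against the rest, which points to a structure of the samples other than the groups, though edgeR called 0 circles in it.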

How the results depend on the processing

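The rescalings of deposited values, the length corrections, DESeq2's unadjusted threshold, the leave-outs with edgeR and the removal of the 2 libraries under 5000 reads were chosen after the data were seen. edgeR with its settings was the count test of the design, and became an alternative once the unit was known. The other alternatives were chosen before. Except where stated, the cause of a change was not tested. With limma, 1 circle changed. The count was 152 at an unadjusted p under 0.05 with a 2-fold change and 23 with DESeq2. At the unadjusted threshold it was 252 with DESeq2. The nominal chance count at that p, about 1369.1, takes in all 27382 circles with a p. As 12725 circles of the table rest on a single read, it is too high for comparison. The count was 236 (136 higher, 100 lower) with limma-voom, 94 with edgeR and 1037 of 5809 tested circles without the 2 libraries under 5000 reads. It was 0 with limma under a filter of 10 reads in 4 libraries (16 of 349 at an unadjusted p under 0.05), after TMM rescaling (119) and with the length trend removed (341). It ran from 0 without TAC replicate 1 to 41 without TAC replicate 2, with 6 without sham replicate 2, and was 1 without each other library. For hosts limma's 1 became 90, 42 with DESeq2, 210 with limma-voom, 84 with edgeR and 221 without the shallow libraries, 4 with a pseudocount 10 times smaller or with total reads, and 0 under the filter of 10 reads (19 at an unadjusted p under 0.05) and TMM rescaling (46). It ran from 1 to 28 (without TAC replicate 2), with 6 without sham replicate 2.

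The edgeR count of 94 circles was 82 with RLE, 99 with TMMwsp, 99 without robust fitting, 61 with total reads only, 2 with a filter of 1 read in 2 libraries (10500 circles tested), 20 with 10 reads in 4 libraries (349 tested), 344 without the 2 shallow libraries and 25 with the length offset. Leaving out 1 library gave 0 (without TAC replicate 3) to 248 (without sham replicate 2), with 62, 39 and 34 without sham replicates 1, 3 and 4 and 9, 230 and 9 without TAC replicates 1, 2 and 4. The edgeR count of 84 hosts was 23 with 1 read in 2 libraries, 46 with 10 reads in 4 and 299 without the 2 shallow libraries. It ran from 11 (without TAC replicate 1 or 3) to 230 (without sham replicate 2), with 47, 19 and 20 without sham replicates 3 and 4 and TAC replicate 4.

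Of the 16 gene lists tested 1 passed. This was 0 with an estimated correlation, with fry, with edgeR sums and with the length trend removed, and 2 without the shallow libraries. Leaving out 1 library gave 0 (without TAC replicate 4) to 2 (without sham replicate 2 or TAC replicate 2). The sarcomere median of 1.20 lost its call with an estimated correlation (1.20, adjusted p = 0.994), fry (1.20, adjusted p = 0.978) and edgeR (0.86, adjusted p = 0.221), and was −0.017 on circles with the length trend removed (0.998 on circles without that step, call kept). Left-out libraries gave 0.35 (without TAC replicate 4, call lost) to 1.85.

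Scaling moved the median log2 fold change of all circles from 0.15 to 0.06 with TMM, −0.05 with TMMwsp and −0.09 with total reads, and of hosts from 0.13 to 0.06, −0.07 and −0.11. In edgeR it was −0.02 with TMM and 0.23 with RLE. Of the 27 circles and hosts run under each setting that kept them, signs turned in 6. Members of the gene lists were compared between limma and edgeR only, where Smad4 went to 0.56, Utrn to 0.05, Usp3 to 0.38 and Ano1 to −0.23. With the length trend removed, Ogdh was at 0.31, Hipk3 at −1.24 and Camk2d at −0.63. Rad52 was at 0.54 with DESeq2, 0.98 with limma-voom, 0.60 with edgeR and 1.97 without the shallow libraries, and Mlip at 0.42, 0.44, 0.30 and 1.20. Hipk3 was at −0.71 with the smaller pseudocount, −0.10 with TMMwsp and −0.24 with total reads, and Fndc3b at −0.14 with edgeR, −0.10 with TMMwsp and −0.14 with total reads. Left-out libraries gave −0.58 to 0.041 for Ogdh, −1.88 to 1.36 for Rad52, −0.82 to 2.33 for Hipk3, −1.73 to 0.83 for Mlip, −0.42 to 1.11 for Camk2d and −1.11 to 1.62 for Fndc3b. The difference in detected circles, 2295.5, was −13.7 with libraries thinned to 1119 reads, −523.5 at 2 reads and −888.5 at 5 reads. That in total reads was −17836.5, from −30081 to 1978 (without sham replicate 4) with 1 library left out. The differences in the share of the 10 most abundant circles (0.69 to 2.30 percentage points) and of intronic circles (0.44 to 0.64) kept their sign without each library. The ratio of circular to linear RNA was not run. Depth limits what the 2 shallow libraries can show, as 567 and 1830 circles were detected there.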

Other observations

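The length offset for edgeR was chosen after the results were seen. With it, 6 circles were higher in TAC, those of Pdlim5 of the Z-disc (log2 fold change 3.68 ± 0.78), Shoc2 of Ras signalling (3.52 ± 0.96), Zfp609 (2.94 ± 0.76), Ehbp1 (2.80 ± 0.68), Zfp148 (2.63 ± 0.66) and Elk3, an ETS factor (2.40 ± 0.61), each called without the offset too. The 19 lower circles of the 25 included Uxs1 (−3.72 ± 1.02), the fatty acid transporter Cd36 (−3.70 ± 0.80), the spliceosome gene Prpf6 (−3.39 ± 0.91), Eed of Polycomb repressive complex 2 (−2.88 ± 0.72), Ube2d2a (−2.19 ± 0.57) and Cpeb3 (exons 8 to 10, −2.04 ± 0.55). Adjusted p ran from 0.0246 for Cd36, Fam126a, Pdlim5 and Pik3c2a to 0.0475 for Arhgap32, and the rank correlation of fold change with length across 713 circles went from 0.620 to 0.113, circles not being independent replicates.

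Exon 2 circles of Slc8a1, Hipk3, Zfp609 and Shoc2 hold the start codon of their gene, with 1799, 1097, 747 and 703 nt of coding sequence, while that of Nfix does not.

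The table was ordered in 3 blocks of 94, 27137 and 160 circles. All 160 of the last had an unadjusted DESeq2 p under 0.05 and a rise of at least 2-fold on recomputation from the recovered reads, and 92 of the first a fall by the same rule, with no p for the other 2. Of these 252 circles 23 passed after adjustment. Over all circles DESeq2 gave 252 at an unadjusted p under 0.05. The nominal chance count of about 1369.1 is too high for comparison, as it takes in circles of a single read.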
